A study of Arabidopsis thaliana with 16 samples.

How the data were processed

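Per the label protocol, 6 µg of total RNA per sample was turned into biotin-labelled cRNA and hybridised to an Affymetrix array. The deposited values were signals per probe set on a log2 scale, normalised by the authors with RMA, which corrects the background, equalises the distributions of the arrays by quantiles and summarises the probes of each probe set. The submitters' processing notes name RMA and limma; their versions are not given in the sources used here. The values of the 16 arrays ran from 3.25 to 14.7 with array medians from 6.07 to 6.19, and no further scaling, filter or pseudocount was applied. Of the 22810 probe sets, 64 were controls and the other 22746 were tested.

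Genes were named from the probe set annotation given with the array and from the RefSeq annotation of assembly TAIR10.1 (Columbia), used for names and for telling nuclear from organelle-encoded genes and not for coordinates. In a locus identifier such as AT5G48570 the digit after AT is the chromosome. The annotation assigned 13513 probe sets to 1 gene, 503 to several genes and 8730 to none. Genes were therefore named for 13513 probe sets only, and 11799 of the 13356 genes with a kept probe set had no symbol other than their locus.

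The tests used R 4.3.3 and limma 3.58.1. One linear model with 4 group means was fitted to all 16 arrays (lmFit and eBayes, 12 residual and 4.21 prior degrees of freedom). Each of the 6 comparisons was tested 2-sided, with Benjamini-Hochberg adjustment over the 22746 probe sets of that comparison. A probe set was called at an adjusted p under 0.05, and "rose" and "fell" are used of called values. Values of log2 changes are given with their standard error from limma, and group levels with the standard deviation of 4 arrays. The arrays' number limits the precision of each value.

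The comparisons, the model, 28 gene lists and the rule for naming genes were chosen before the data were examined. The rule took the 10 largest rises and 10 largest falls among called probe sets with 1 gene in each comparison with the baseline and 5 of each in the other comparisons. It also took up to 2 rising and 2 falling called members of each list in each comparison with the baseline, and 13 genes whatever their values. Only RCA of those 13 had a probe set with a name; the heat shock factor HSFA2, the chaperones HSP101, HSP90.1, HSP70-4 and HSP21, and the clock genes CCA1, LHY, PRR7 and TOC1 were among the others. Genes named from outside the rule stand in the closing observations and are marked there. In each comparison the largest called fall lay in a probe set not assigned to 1 gene, so the named falls are not the largest. It was −4.87 at 30% inhibition against the baseline, where the largest named fall was −3.93. Between the inhibited states it was −2.74, against −1.89 for the largest named fall.

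The 28 lists held 489 distinct loci, of which 73 had a named probe set. Only these 73 are called measured below, and the other loci may have probe sets that the annotation left without a gene. The 14 lists with at least 3 measured members were tested with limma's camera at a preset correlation of 0.01, 1 probe set per gene (the brightest), and adjusted over 84 tests. In all, 36 of the 84 tests passed, against 17 with an estimated correlation and 63 with fry, which asks only whether the members move, on balance, one way. A further 30 lists (genes encoded in the chloroplast, genes encoded in the mitochondrion, and families of at least 8 genes sharing a symbol stem) were defined by rule once the annotation was known and a few values had been seen, and were adjusted over 180 tests of their own, of which 26 passed, 4 with an estimated correlation and 96 with fry.

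Measures of the arrays themselves (the 25S rRNA control, the 3′ minus 5′ differences of control genes and list means) were compared by 2-sided exact permutation tests on the difference of means. With 4 arrays against 4 there are 70 assignments and the smallest possible p is 0.0286. These p-values were adjusted over 54 tests.

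The alternatives tried were an intensity-trended and a robust eBayes prior, a fit on only the 8 arrays compared, leaving out the dimmest 33.3% of probe sets, centring arrays on their medians, a repeated quantile normalisation, array weights, leaving out each array, the replicate number as a block or as a random effect, 1 probe set per gene, the mean probe set per gene, an estimated correlation, fry, and stricter thresholds. The 25S rRNA control as a covariate was added after that signal had been seen. That signal overlaps with the state: it ran from 5.52 to 6.41 in the baseline and optimum arrays and from 8.67 to 11.4 at 30% inhibition. A call that ended with this covariate may therefore reflect a wider standard error, and does not show that the 25S signal accounts for the change. The gene JMT at 20% inhibition changed by −0.32 without the covariate and by −0.34 with it, yet its call ended. Other estimates shrank with it. Against the baseline at 20% inhibition, the photosystem gene PSBY went from −0.17 to −0.06 and the flavonoid gene UF3GT from 0.30 to 0.17. List tests under the robust prior and the random effect used cameraPR on the moderated statistics.

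As a check of the model, 50 simulated probe sets were changed at each size among 22746, with spreads like those of the arrays. It recovered 84% of changes of 0.5 on the log2 scale and 100% of changes of 1, 2 and 4, with 6 false calls in that comparison and 0 in one without changes. In simulated list tests, 1 of 50 unchanged lists of 10 genes was called. The simulated genes varied independently of each other, so this does not show how the list tests behave where members are correlated.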

Results

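Transcripts were measured on 16 Affymetrix arrays, each hybridised with RNA from leaf tissue of Arabidopsis thaliana, line Columbia. The plants had grown at 22 °C with a 10 h photoperiod, light of 350 µmol m-2 s-1 and 60% humidity. Leaves were taken at 4 states of photosynthesis along a curve in which the temperature was raised from 22 to 42 °C by 2 °C every 10 min after 20 to 30 min of stabilisation, each curve lasting 3 to 4 h. The states were a baseline at the growth temperature, the optimum of photosynthesis, and the points at which photosynthesis lay 20% and 30% below that optimum. Each state had 4 arrays (n = 4 for every group value), and per the labels the replicates are leaf samples of randomly collected plants, so the p-values measure the spread between these samples. The leaf temperatures of the states are not given in the labels. A later state was also later in the curve, so temperature, time in the curve and time of day cannot be separated in any comparison.

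Among the 3 successive steps, the step from the optimum to 20% inhibition had the most called probe sets. A first principal component with 74.5% of the variance separated baseline and optimum from both inhibited states, and a second with 8.07% followed. Correlations between arrays ran from 0.988 to 0.998 within states and from 0.942 to 0.994 between them. By the F test over the 4 states, 12278 of 22746 probe sets (54.0%) varied. Of 11146 probe sets called at any of the 3 successive steps, 6318 were called only between optimum and 20% inhibition, 1251 only between baseline and optimum, and 315 only between 20% and 30% inhibition. Probe sets called at both of the first steps kept their direction in 1726 cases and turned in 690. Successive steps share the arrays of the state between them with opposite signs, so noise in those arrays favours turns over kept directions. With the 25S rRNA control as a covariate, which overlaps with the state, the count called only between optimum and 20% inhibition was 4068.

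**Figure D1:**
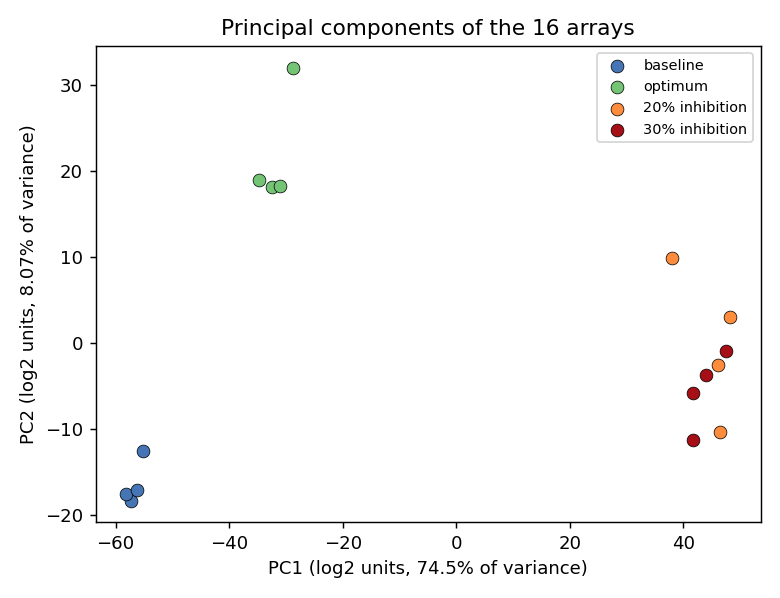
Positions of the 16 arrays on the first and second principal components of the log2 RMA signals, coloured by state, with 74.5% and 8.07% of the variance. Both inhibited states lie apart from baseline and optimum on the first component.

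**Figure D2:**
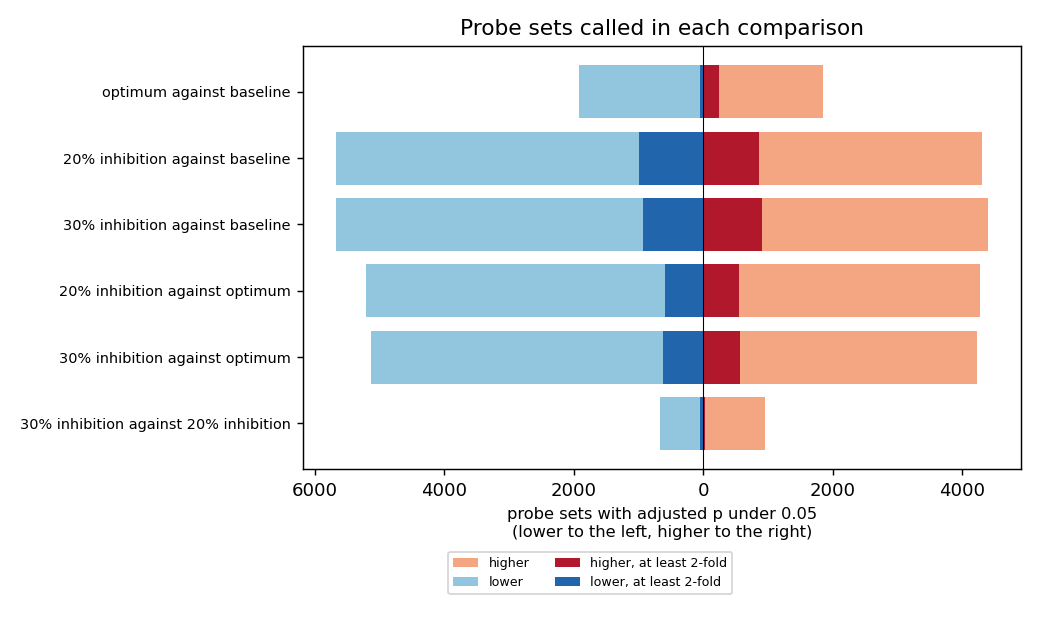
Number of probe sets with an adjusted p under 0.05 in each comparison, lower to the left and higher to the right, with the part changed at least 2-fold in dark colours. The counts range from 1629 between the inhibited states to 10067 between 30% inhibition and baseline.

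The comparison of the optimum with the baseline asks what had changed in the leaf before photosynthesis declined. Chaperone transcripts already stood far above the baseline. AT5G48570, an FKBP-type peptidyl-prolyl isomerase, rose 44.1-fold (log2 5.46 ± 0.16 SE, adjusted p = 6.8e-13), from 5.19 ± 0.30 to 10.65 ± 0.42 (SD). The DnaJ-type co-chaperone AT2G20560 rose 21.2-fold (4.41 ± 0.12), the mitochondrial small heat shock protein AT5G51440 13.6-fold (3.77 ± 0.16) and the HSP90 co-chaperone Hop3 (AT4G12400) 11.8-fold (3.56 ± 0.19), the last 2 folds approximate since their baseline signals (3.90 and 4.18) were near the lowest of the arrays. The RING finger genes AT1G26800 and AT1G14200 rose 10.2-fold and 9.54-fold. The falls were smaller: the cysteine proteinase gene AT2G27420 fell 5.75-fold (−2.52 ± 0.11), the sucrose-phosphate synthase ATSPS4F (AT4G10120) 2.82-fold (−1.50 ± 0.17), the wax ester synthase WSD1 (AT5G37300) 2.56-fold and the sugar transporter SWEET2 (AT3G14770) 2.54-fold.

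At the optimum 7 of 9 measured chaperones rose (8 adjusted over the list alone; median 1.74, adjusted p = 1.5e-19), with Fes1A (AT3G09350), a partner of cytosolic HSP70, 8.78-fold higher. Of 7 small heat shock proteins 3 rose (4 adjusted over the list alone; median 0.58): AT5G51440, the cytosolic AT2G29500 (3.65 ± 0.11) and the peroxisomal AT5G37670 (1.37 ± 0.13). The endoplasmic reticulum member ATHSP22.0 (AT4G10250) did not pass, with a log2 change of −0.08 ± 0.11, nor did AT1G52560 with 0.02 ± 0.16. Of 4 endoplasmic reticulum folding genes 3 rose (4 adjusted over the list alone), among them the stress sensor BZIP28 (AT3G10800; 0.81 ± 0.06) and the co-chaperone ATERDJ3B (AT3G62600; 0.64 ± 0.08). Of 3 genes for abscisic acid and dehydration 2 rose (3 adjusted over the list alone), COR47 (AT1G20440) 2.56-fold and COR15B (AT2G42530) 1.87-fold. These 4 lists passed with preset and estimated correlations alike, the latter with adjusted p between 0.0035 and 0.039.

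Smaller shifts at the optimum concerned metabolism. Of 3 photorespiration genes 2 fell (3 adjusted over the list alone; camera adjusted p = 0.021, but adjusted p = 0.23 with an estimated correlation): the peroxisomal hydroxypyruvate reductase HPR (AT1G68010; −0.34 ± 0.07) and the glycerate kinase AT1G80380 (−0.31 ± 0.07). Of 4 antioxidant enzymes 2 fell, also over the list alone, the glutathione reductases GR1 (AT3G24170; −0.50 ± 0.08) and GR (AT3G54660; −0.44 ± 0.09), with a list adjusted p = 0.016 (adjusted p = 0.064 with an estimated correlation). The photorespiration call also ended when the dimmest genes were left out (adjusted p = 0.060). The starch list passed at adjusted p = 0.047 with 2 of 4 members higher (2 rose and 1 fell adjusted over the list alone), the phosphoglucan, water dikinase PWD (AT5G26570; 0.74 ± 0.06) and the disproportionating enzyme DPE1 (AT5G64860; 0.72 ± 0.07), both acting in starch breakdown. That list call did not hold with an estimated correlation (adjusted p = 0.25), without the dimmest genes (0.16), with array weights (0.076) or when any of 8 single arrays was left out, the optimum replicates 2 and 3 among them (0.065 and 0.084). Also among the 8 were 20% inhibition replicates 1, 2 and 3 and 30% inhibition replicates 1 and 3, which are not part of this comparison. Without each of them the median was unchanged at 0.29, and only the spread and the adjustment moved p (0.051 to 0.087).

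In all, 3770 probe sets were called between optimum and baseline, 1852 higher and 1918 lower (49.1% higher). Only 294 of them changed at least 2-fold, 245 upwards and 49 downwards. The Calvin-Benson list (median −0.28, adjusted p = 0.094; 2 of 3 lower, also over the list alone, SBPASE not without baseline replicate 1 (0.061) or optimum replicate 4 (0.083) and PRK not without baseline replicate 2 or 4 (0.057, 0.054) or optimum replicate 4 (0.057)), the antenna list (0.95), the photosystem list (0.95), chlorophyll synthesis (0.19), flavonoid synthesis (0.36), expansins and xyloglucan enzymes (0.65) and cytosolic ribosomal proteins (0.096) did not pass; the ribosomal list passed upwards without baseline replicate 3 (0.018) or optimum replicate 3 (0.028). Adjusted over the list alone, 1 of 3 antenna genes and 1 of 4 flavonoid genes fell, 1 chlorophyll gene rose and 1 fell, 2 of 5 expansins and xyloglucan enzymes rose and 1 fell, and 0 photosystem and ribosomal genes were called. Within these lists the protochlorophyllide oxidoreductase PORB (AT4G27440) rose 1.87-fold and the flavonoid glucosyltransferase UGT78D2 (AT5G17050) fell 1.69-fold.

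The comparisons of the inhibited states with the baseline ask what accompanied the loss of photosynthesis. At 20% inhibition small heat shock proteins were among the genes with the highest fold values. The cytosolic AT1G53540 rose 723-fold (log2 9.50 ± 0.23, adjusted p = 2.5e-15), from 4.44 ± 0.22 to 13.94 ± 0.27 (SD), AT5G51440 549-fold (9.10 ± 0.16), AT2G29500 514-fold (9.01 ± 0.11) and AT5G48570 410-fold (8.68 ± 0.16). The signals of all arrays ran from 3.25 to 14.7, so AT1G53540 and AT5G51440 (3.90 at baseline) went from near the lowest to near the highest signals, and the folds of such genes and their order are approximate. ATHSP22.0, not called at the optimum, was 173-fold higher (7.43 ± 0.11). Among the falls were AT2G27420 (14.7-fold, −3.88 ± 0.11), the leucine-rich repeat receptor kinases AT5G59670 (−3.59 ± 0.15) and AT1G51805 (5.70-fold), ATSPS4F (6.67-fold) and the calmodulin-like AT2G41090 (4.23-fold). AT5G59670 ended near the lowest signals, so its fall may be larger than this value.

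Of the 7 small heat shock proteins 6 rose at 20% inhibition, also over the list alone (median 7.94, adjusted p = 1.7e-10). All 9 chaperones rose, also over the list alone (median 2.83), and all 4 endoplasmic reticulum folding genes rose, also over the list alone (median 1.88), ATERDJ3B 5.34-fold, BZIP28 3.91-fold and the calreticulin CRT1b (AT1G09210) 3.45-fold. These 3 lists held with an estimated correlation (adjusted p at most 0.039). All 3 genes for abscisic acid and dehydration rose, also over the list alone, COR47 4.61-fold and COR15B 2.76-fold (list adjusted p = 0.0091; adjusted p = 0.12 with an estimated correlation). In 3 of the 4 arrays of this state the signal of the 25S rRNA control, a probe set for a non-polyadenylated transcript, was above every baseline array, as given with the organelle transcripts.

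**Figure D3:**
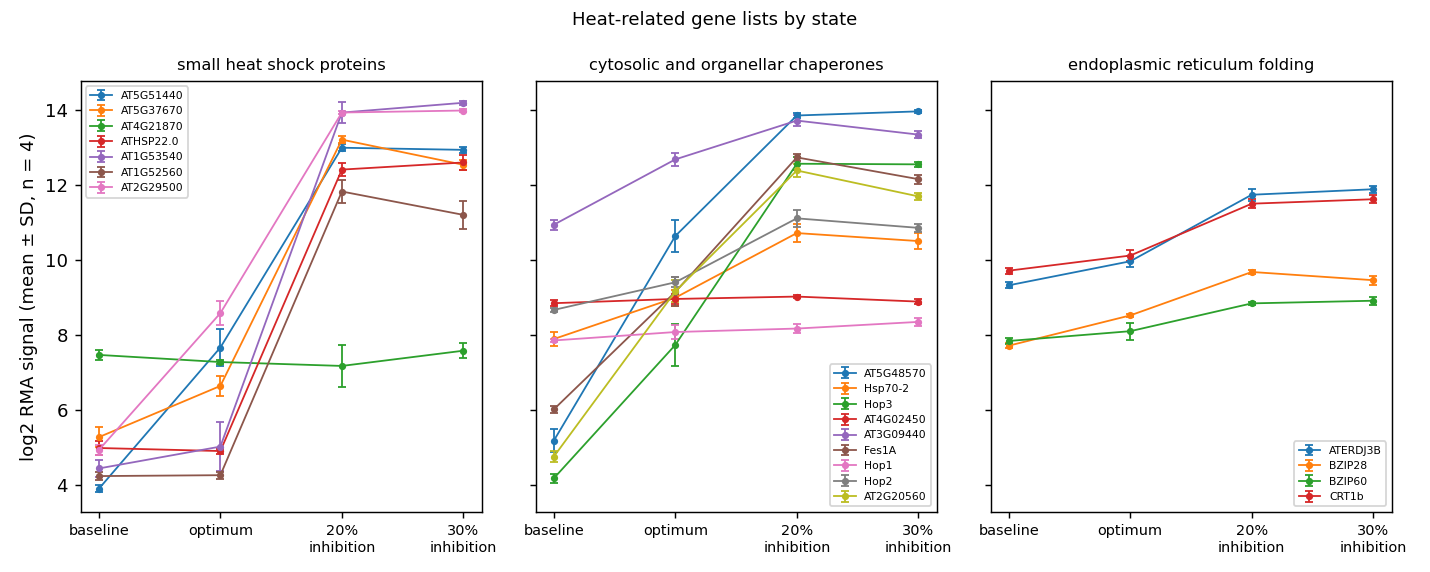
Log2 RMA signal of each measured member of 3 heat-related lists by state, as mean with SD bars over 4 arrays. AT1G53540 stands near 4.44 at baseline and 5.03 at the optimum and at 13.94 at 20% inhibition.

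Genes of carbon fixation and photorespiration were lower. All 3 measured Calvin-Benson genes fell at 20% inhibition, also over the list alone: sedoheptulose-bisphosphatase SBPASE (AT3G55800; −0.84 ± 0.08), phosphoribulokinase PRK (AT1G32060; −0.84 ± 0.08) and the Rubisco activase RCA (AT2G39730; −0.20 ± 0.04). RCA read 14.62 at baseline, at the upper end of the array signals, so the size of its change cannot be read from this probe set. All 3 photorespiration genes fell, also over the list alone, HPR by a log2 change of −0.68 ± 0.07 and AT1G11860, a glycine cleavage subunit, by −0.73 ± 0.09. The lists passed at adjusted p = 0.014 and 0.013, and neither held with an estimated correlation (adjusted p = 0.20 and 0.21) or without the dimmest genes (0.088 and 0.073). In the antenna list only LHCB4.3 (AT2G40100) of 3 members fell (−0.87 ± 0.13), also over the list alone, and in the photosystem list 2 of 5 fell (3 adjusted over the list alone), among them the ATP synthase subunit ATPC1 (AT4G04640; −0.29 ± 0.05). The other, PSBY (−0.17 ± 0.06, adjusted p = 0.024), ended with arrays centred (0.090), 8 arrays (0.058), the 25S covariate (0.55) and without baseline replicate 2 or 3 (0.058, 0.051) or 20% inhibition replicate 2 or 4 (0.072, 0.065). Neither list passed (adjusted p = 0.35 and 0.16).

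Among antioxidant enzymes GR1 (−1.45 ± 0.08) and GR (−1.20 ± 0.09) fell at 20% inhibition (4 of 4 adjusted over the list alone), with a list adjusted p = 0.014 that did not hold with an estimated correlation (adjusted p = 0.057) or without the dimmest genes (0.073). In the starch list 3 of 4 rose and 1 fell, also over the list alone: PWD 2.85-fold and DPE1 2.33-fold higher, and APL3 (AT4G39210), a subunit of the ADP-glucose pyrophosphorylase of starch synthesis, 1.77-fold lower; the list did not pass (adjusted p = 0.085). PORB was 1.94-fold higher and the chlorophyll methyltransferase CHLM (AT4G25080) 1.53-fold lower in a chlorophyll list that did not pass (0.93; 1 rose and 1 fell adjusted over the list alone). EXPA8 (AT2G40610), an expansin, fell 5.06-fold in a list in which 2 of 5 fell, also over the list alone (0.47), and UGT78D2 fell 2.11-fold in the flavonoid list (0.44; 1 rose and 1 fell adjusted over the list alone). The other expansin call, EXPA4 (−0.50), ended with 8 arrays (0.068), array weights (0.075) and without baseline replicate 2 or 3 (0.058, 0.072). It also ended without 20% inhibition replicate 1 (0.052) or replicate 3 (0.067), where its change was −0.28. Of 4 cytosolic ribosomal proteins 3 fell, also over the list alone, without a list call (0.33). The calls of AT3G09200 and AT5G02870 ended without baseline replicate 3 (0.091 for both). That of AT5G02870 also ended with array weights (0.056), the 25S covariate (0.092) and without 20% inhibition replicate 3 or 4 (0.050, 0.053).

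The counts at 20% inhibition were 9976 probe sets against the baseline, 4303 higher and 5673 lower (43.1% higher, 51.5% with arrays centred on their medians), with 1850 changed at least 2-fold (855 up, 995 down). Replicate 3 of this state stood apart for several genes: the TIR-domain gene AT3G04210, 7.35-fold lower than baseline over the group, read 7.51 in that array and 4.82 to 5.13 in the other 3.

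At 30% inhibition small heat shock proteins and chaperones were among the genes with the highest fold values. AT1G53540 was 867-fold above the baseline (9.76 ± 0.23, adjusted p = 1.9e-15), AT2G29500 533-fold, AT5G51440 528-fold, AT5G48570 442-fold and Hop3 333-fold; these folds too start near the lowest array signals (Hop3 at 4.18) and are approximate. Among the falls were AT2G27420 (15.2-fold, −3.93 ± 0.11), AT5G59670 (12.8-fold), ATSPS4F (12.6-fold), the glutaredoxin AT3G62950 (7.15-fold, −2.84 ± 0.37), AT2G41090 (6.52-fold) and the lipid transfer protein AT5G55450 (6.42-fold). AT5G59670 and AT3G62950 ended at 4.14 and 3.94, near the lowest signals, so their falls may be larger than these values. WSD1 fell 4.47-fold and SWEET2 4.65-fold.

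Of the 7 small heat shock proteins 6 rose at 30% inhibition (median 7.62), as did 8 of 9 chaperones (2.61) and 4 of 4 endoplasmic reticulum folding genes (1.83), with the same counts adjusted over the list alone; these lists held with an estimated correlation (adjusted p at most 0.039). The 3 genes for abscisic acid and dehydration rose, also over the list alone, COR47 4.73-fold (list adjusted p = 0.0053; adjusted p = 0.10 with an estimated correlation). All 4 antioxidant enzymes fell, also over the list alone, GR1 3.15-fold and GR 2.69-fold, in a list that held both ways (adjusted p = 0.0082 and, with an estimated correlation, 0.042). The 3 Calvin-Benson genes and the 3 photorespiration genes fell, also over the list alone, SBPASE 1.93-fold, PRK 1.73-fold and HPR 1.60-fold (list adjusted p = 0.020 and 0.012; adjusted p = 0.21 for both with an estimated correlation, 0.096 and 0.060 without the dimmest genes). RCA, again at the upper end of the signals, was called lower (adjusted p = 0.0086), a call that ended with the 25S rRNA control as a covariate (0.067). Its log2 change was −0.155 without and −0.150 with that covariate.

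Lists that did not pass at 30% inhibition were starch (adjusted p = 0.095; 3 rose and 1 fell, also over the list alone, with PWD 3.08-fold higher and APL3 2.44-fold lower), antenna (0.35; LHCB4.3 fell 2.24-fold, the 1 call also over the list alone) and photosystems (0.19; 3 fell, also over the list alone, of which PSBY ended without baseline replicate 2 (0.056), 30% inhibition replicate 2 or 3 (0.069, 0.061) and with the 25S covariate (0.45)). Chlorophyll synthesis (0.93; PORB 1.97-fold higher, CHLM 1.65-fold lower), flavonoids (0.87; UGT78D2 1.93-fold lower), expansins and xyloglucan enzymes (0.65; EXPA8 5.31-fold lower) and cytosolic ribosomal proteins (0.32; 3 of 4 fell) had the same counts adjusted over the list alone, 1 rise and 1 fall in chlorophyll synthesis and in expansins. In all 10067 probe sets were called, 4394 higher and 5673 lower (43.6% higher), with 1848 changed at least 2-fold (909 up, 939 down).

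Transcripts encoded in the mitochondrion were higher at both inhibited states. Of 11 measured genes 10 rose in each, with a median log2 change of 2.18 at 20% and 2.72 at 30% inhibition and −0.08 at the optimum. The complex I genes nad6 and nad4L rose 21.1-fold and 19.6-fold (SE of log2 0.10 and 0.11) at 30% inhibition, approximate values from low baseline signals of 4.72 and 4.53, and the cytochrome oxidase gene cox2 rose 6.59-fold (2.72 ± 0.08), after a small fall at the optimum (−0.47 ± 0.08), the only called member there. The list passed at adjusted p = 4.6e-10 and 3.5e-10 at 20% and 30% inhibition, and with an estimated correlation at 0.030 in both. Of 69 genes encoded in the chloroplast 42 fell and 1 rose at 20% inhibition (median −0.41), and 24 fell and 1 rose at 30% (median −0.24). The subunit gene ndhH of the NADH dehydrogenase-like complex was 2.96-fold and 2.37-fold lower. The chloroplast mean per array changed by −0.39 ± 0.12 (SE) at 20% inhibition (exact permutation p = 0.0571, 0.14 adjusted over 54 tests). At 30% it changed by −0.248 ± 0.114 (exact permutation p = 0.114, 0.229 adjusted). Neither passed, so a fall of this mean across arrays is not established. At 30% inhibition replicates 2, 3 and 4 (11.24, 11.21 and 11.196) lay within the baseline range of 11.14 to 11.63, and replicate 1 below it. The rise of rps14 at 20% ended without baseline replicate 3 (0.056) or 20% inhibition replicate 2 (0.063) and with the 25S covariate (0.11). That of psbA at 30% ended without baseline replicate 3 (0.094), without 30% inhibition replicate 1, 2 or 4 (0.069, 0.051, 0.061) and with the 25S covariate (0.18). The chloroplast list calls at 20% and 30% (adjusted p = 8.3e-06 and 0.0079) did not hold with an estimated correlation (adjusted p = 0.54 and 0.74), and the latter also ended without baseline replicate 1 (0.065) or the dimmest genes (0.057). At the optimum the chloroplast list did not pass (0.28), but it passed downwards without baseline replicate 3 (median −0.18, adjusted p = 0.0020) and with array weights (0.027).

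The log2 signal of the 25S rRNA control was 5.89 ± 0.38 (SD) at baseline, 5.98 ± 0.35 at the optimum, 10.4 ± 3.62 at 20% inhibition and 9.95 at 30% inhibition, where the arrays ran from 8.67 to 11.4. At 30% inhibition it exceeded the baseline by 4.06 ± 0.58 (SE), 16.7-fold, in 4 of 4 arrays (exact permutation p = 0.0286, the smallest possible; 0.0857 adjusted over 54 tests). At 20% inhibition the difference was 4.49 ± 1.82 (exact permutation p = 0.143; 0.249 adjusted), since replicate 3 of that state read 5.25. The mean 3′ minus 5′ difference of the actin, GAPDH and ubiquitin controls changed by 0.053 ± 0.051 at 30% inhibition (exact permutation p = 0.371; 0.478 adjusted). Its members went different ways: actin by 0.32 ± 0.09 (exact permutation p = 0.0286; 0.0857 adjusted), GAPDH by −0.12 ± 0.06 and ubiquitin by −0.04 ± 0.04.

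**Figure D4:**
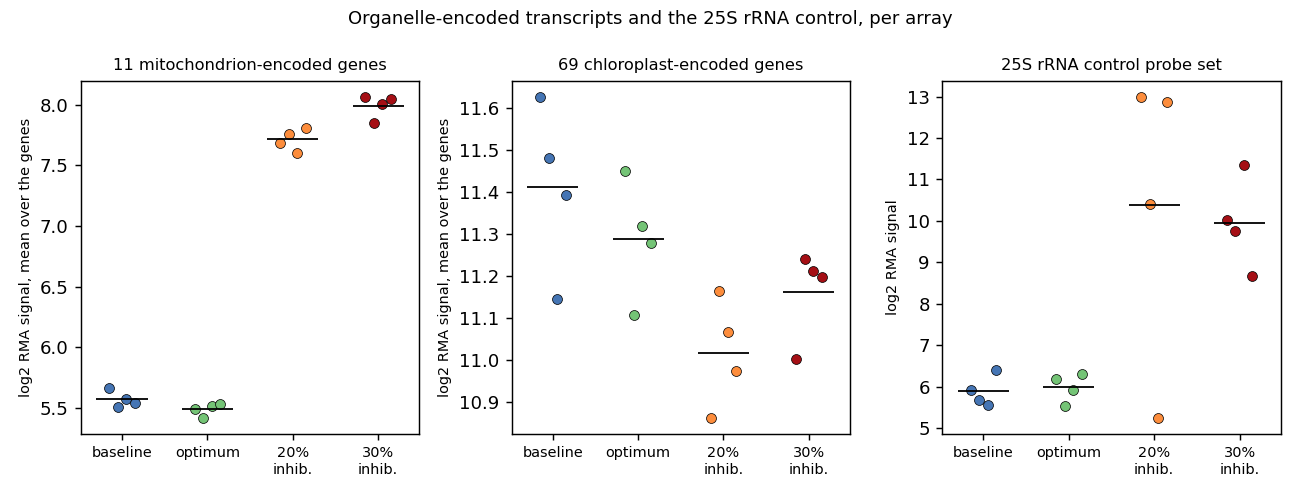
Mean log2 RMA signal of 11 mitochondrion-encoded and 69 chloroplast-encoded genes and the signal of the 25S rRNA control in each array, with the state mean as a bar. In 20% inhibition replicate 3 the 25S control reads 5.25, below the lowest baseline array (5.55), while its mitochondrial mean is 7.60.

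The comparisons of the inhibited states with the optimum ask what changed after photosynthesis had passed its peak. Small heat shock proteins rose: AT1G53540 rose 482-fold at 20% and 578-fold at 30% inhibition, AT1G52560 190-fold and 123-fold, ATHSP22.0 182-fold and 208-fold. The GTP-binding protein AT1G72660 rose 91.6-fold and 76.5-fold. All are approximate since their optimum signals (4.26 for AT1G52560) were near the lowest of the arrays. The receptor kinase AT1G35710 fell 7.99-fold (−3.00 ± 0.24) and 9.09-fold (−3.18 ± 0.24), and AT5G55450 6.47-fold and 9.60-fold. Of the small heat shock proteins 6 of 7 rose in both comparisons, of the chaperones 7 and 8 of 9, and of the endoplasmic reticulum folding genes 4 of 4, with the same counts adjusted over the list alone; all held with an estimated correlation (adjusted p at most 0.050). Of the mitochondrion-encoded genes 10 of 11 rose in both, the list holding with an estimated correlation (adjusted p = 0.030).

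Falling lists against the optimum were the Calvin-Benson cycle (3 of 3 fell at 20% and 2 of 3 at 30% inhibition; 3 each adjusted over the list alone), photorespiration (3 of 3 in both, also over the list alone), antioxidant enzymes (2 of 4 in both, also over the list alone) and cytosolic ribosomal proteins (3 of 4 in both, also over the list alone; AT3G09200 −0.44 ± 0.11 and −0.53 ± 0.11). Their adjusted p lay between 0.018 and 0.045 and none held with an estimated correlation (adjusted p from 0.065 to 0.37) or without the dimmest genes (0.092 to 0.17). The call of RCA at 20% inhibition ended with arrays centred (0.18), a repeated quantile normalisation (0.12), 8 arrays (0.060) and the 25S covariate (0.11). With that covariate the calls of HPR (0.096 and 0.057) and AT1G80380 (0.35 and 0.082) ended at both states, as did the list calls of photorespiration at both (0.14 and 0.081) and of the Calvin-Benson cycle at 30% (0.053). AT1G80380 at 20% inhibition also ended with arrays centred (0.12) and without optimum replicate 2 or 3 (0.055, 0.083) or 20% inhibition replicate 4 (0.074).

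Photorespiration at 20% inhibition also ended with arrays centred (0.051) and without optimum replicate 2 or 3 (0.061, 0.075) or 20% inhibition replicate 2 or 4 (0.053, 0.066). The antioxidant call at 20% inhibition ended without optimum replicate 2 or 3 (0.061, 0.062) or 20% inhibition replicate 3 (0.086). The ribosomal call at 20% inhibition ended without optimum replicate 2 or 4 (0.061, 0.068) or 20% inhibition replicate 3 (0.094), and that at 30% without optimum replicate 2 or 4 (0.061, 0.067) or 30% inhibition replicate 4 (0.068). The chloroplast-encoded genes passed in both (26 and 17 of 69 fell; adjusted p = 2.6e-05 and 0.028), though not with an estimated correlation (adjusted p = 0.56 and 0.79), and the call at 30% ended without optimum replicate 1 (0.075) or 30% inhibition replicate 1 (0.091) and with the 25S covariate (0.13). The lists for abscisic acid and dehydration (adjusted p = 0.13 and 0.078; 0.045 at 30% without 30% inhibition replicate 2), starch (0.12 and 0.19), antenna (0.24 and 0.21), photosystems (0.11 and 0.13), chlorophyll synthesis (0.38 and 0.26), flavonoids (0.52 and 0.95) and expansins and xyloglucan enzymes (0.13 and 0.23) did not pass. Over the list alone, 2 of 3 abscisic acid genes rose in both, 3 starch genes rose and 1 fell, 1 antenna gene and 2 photosystem genes fell, 1 and 2 chlorophyll genes fell, 1 flavonoid gene rose and 1 fell, and 1 expansin or xyloglucan gene rose and 3 fell. In all 9477 probe sets were called at 20% inhibition (4269 higher, 5208 lower) and 9364 at 30% (4227 higher, 5137 lower), of which 1143 and 1185 changed at least 2-fold. The higher shares, 45.0% and 45.1%, depended on the scaling and were 62.1% and 53.6% with arrays centred on their medians.

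The comparison of 30% with 20% inhibition asks what changed as photosynthesis declined further. The CCT-domain gene AT1G07050 rose 5.48-fold (2.45 ± 0.17, adjusted p = 2.4e-07), the sulfur-deficiency-induced gene AT1G04770 3.33-fold, P1R1 (AT5G57780) 2.94-fold and the cold-regulated COR27 (AT5G42900) 2.84-fold. AT4G27657 fell 3.70-fold (−1.89 ± 0.23), AT4G27652 3.34-fold, the RING finger genes AT1G14200 and AT5G47610 3.34-fold and 3.30-fold, and AT5G35320 2.82-fold. AT1G14200 and AT5G35320 had risen at both earlier steps. Of 9 chaperones 3 fell (4 adjusted over the list alone), AT2G20560 by −0.69 ± 0.12 and Fes1A by −0.58 ± 0.14, with a list adjusted p = 0.015 (adjusted p = 0.31 with an estimated correlation). Of 7 small heat shock proteins 2 fell, also over the list alone, AT5G37670 by −0.67 ± 0.13 and AT1G52560 by −0.62 ± 0.16, without a list call (0.70). The AT1G52560 call ended with only 8 arrays (0.11) and without 20% inhibition replicate 1 or 4 (0.077, 0.073) or 30% inhibition replicate 2 or 4 (0.074, 0.079). Of 11 mitochondrion-encoded genes 5 rose further, cox2 by 0.61 ± 0.08 and nad6 by 0.59 ± 0.10 (list adjusted p = 0.00067; adjusted p = 0.28 with an estimated correlation). The call of nad4L (0.41) among them ended with 8 arrays (0.073) and array weights (0.058). It also ended without 20% inhibition replicate 2 or 3 (0.054, 0.057) or 30% inhibition replicate 1, 3 or 4 (0.066, 0.089, 0.078). The chloroplast list passed upwards (median 0.12, adjusted p = 0.011) with no called member, and not with an estimated correlation (adjusted p = 0.75) or without 20% inhibition replicate 1 (0.16).

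No other list passed between the inhibited states; the lowest adjusted p was 0.13, for the antioxidant enzymes (0 of 4 called, 2 fell adjusted over the list alone). Among the rest, 1 flavonoid gene rose and 1 endoplasmic reticulum folding gene and 1 starch gene fell, also over the list alone, with 0 calls in the other 8 lists. The folding gene, BZIP28 (−0.22), lost its call with the trended prior (0.059), 8 arrays (0.13), a repeated quantile normalisation (0.077), the replicate block (0.065) and without any of several single arrays. The starch gene, APL3 (−0.47), lost it with 8 arrays (0.053). In all 1629 probe sets were called, 953 higher and 676 lower (58.5% higher, 46.4% with arrays centred on their medians), and 82 changed at least 2-fold, 30 up and 52 down. With only the 8 arrays compared the count was 915, and without 20% inhibition replicate 3 it was 2153.

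In several lists that passed in no comparison with the baseline, the median and the mean had opposite signs: the antenna at the optimum (0.03 and −0.10), chlorophyll synthesis at 20% (−0.03 and 0.10) and 30% inhibition (−0.10 and 0.05), expansins and xyloglucan enzymes at 20% (0.15 and −0.44) and 30% (0.08 and −0.28), and flavonoids at 30% (0.14 and −0.08). In the photosystem list at the optimum both were negative (−0.02 and −0.01) while the test pointed upwards. Between the inhibited states the signs differed for small heat shock proteins (0.05 and −0.06), the antenna (0.01 and −0.09) and expansins and xyloglucan enzymes (−0.07 and 0.16), and the Calvin-Benson mean was −0.000279 with a median of 0.05.

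Lists with fewer than 3 measured members were not tested, and their members are given instead. The heat-acclimation gene HSA32 (AT4G21320) rose 26.4-fold at 20% inhibition and 24.5-fold at 30%, and AT4G13550 of the same list fell at the optimum (−0.50 ± 0.10) and rose at both inhibited states (0.62 ± 0.10 and 0.63 ± 0.10). Of the afternoon and evening clock genes GI (AT1G22770) was measured and rose at all 3 states (0.74 ± 0.07, 1.88 ± 0.07 and 1.92 ± 0.07). Of the warm-temperature and auxin list IAA29 (AT4G32280) rose at 20% inhibition (0.48 ± 0.10). The touch and wound gene STZ (AT1G27730) rose at 20% inhibition (1.88 ± 0.35), and the jasmonate methyltransferase JMT (AT1G19640) fell at all 3 states (−0.46 ± 0.09, −0.32 ± 0.09 and −0.60 ± 0.09), the call at 20% inhibition ending with the 25S covariate (0.057). In the glucosinolate list UGT74B1 (AT1G24100) rose at the optimum (0.35 ± 0.09), fell at 20% inhibition (−0.36 ± 0.09) and rose at 30% (0.31 ± 0.09), each against the baseline. Its call at the optimum ended without baseline replicate 2 or 4 or optimum replicate 1 (0.056, 0.053 and 0.054), and that at 30% with the 25S covariate (0.092). The other member BCAT4 was not called in any comparison. The salicylate-linked WRKY53 was not called either. Of the guard cell markers FMA (AT3G24140) fell at 20% inhibition (−0.42 ± 0.09) and AT1G22690 at both inhibited states (−1.63 ± 0.18 and −1.83 ± 0.18), and of the phloem markers SWEET11 (AT3G48740) fell at all 3 states (−0.48 ± 0.12, −0.88 ± 0.12 and −0.88 ± 0.12). Heat shock factors, morning-phased clock genes, fatty acid desaturases, aquaporins and markers of epidermis and trichomes had 0 members with a named probe set. They may be among the 8730 probe sets to which the annotation assigned no gene, so nothing is known of them here.

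Calls were shared widely between the comparisons with the baseline. Of the probe sets called at the optimum, 2852 were called in the same direction at 20% inhibition (1248 up and 1604 down; 148 opposite) and 2777 at 30% (179 opposite), where independent lists would share 350 up and 478 down and 358 up and 478 down. Between the inhibited states 8297 were shared (3496 up, 4801 down; 22 opposite). Because these comparisons use the same baseline arrays, the baseline was also split into 2 arrays for each side: over the splits, 1624 to 1968, 1559 to 1926 and 6610 to 6735 probe sets were shared. The log2 changes of the 3 pairs correlated at 0.655, 0.631 and 0.956, where unchanged groups simulated against shared baseline arrays gave 0.5001, 0.4995 and 0.4994. Those simulated values follow from the shared arrays where nothing changed, so they do not measure the baseline's part in the observed correlations. The covariances were 0.138, 0.131 and 0.446, against 0.0050 in each simulated pair. With the baseline split, the correlations ran from 0.598 to 0.636, 0.576 to 0.610 and 0.936 to 0.944.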

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

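The tests on the 25S rRNA control and on 20% inhibition replicate 3 were chosen only after their results had been seen; those on the mitochondrion-encoded transcripts and the regroupings of the arrays were not.

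Mitochondrion-encoded transcripts were higher at 30% inhibition than at baseline, with a median log2 change of 2.72 over 11 genes. More labelling of non-nuclear RNA in heated leaves would have raised the chloroplast-encoded transcripts as well, but their median changed by −0.236, and by −0.211 in the 15 of them with a baseline level under 10. The 25S rRNA control, which that explanation would also raise, was higher by 4.06 (exact permutation p = 0.0286, 0.0857 adjusted), so only an increase shared by all such RNA is argued against. RNA degradation would have widened the 3′ minus 5′ difference of the control genes, which changed by 0.053 ± 0.051, although that of actin alone changed by 0.32 ± 0.09 and that of GAPDH by −0.12. The mitochondrial median moved by at most 0.034 under the scalings tried. The deposited values were already equalised by quantiles, and centring removed a shift of at most 0.063. These scalings could therefore move the median only a little, and do not decide whether scaling contributed. Temperature and time in the curve both stay open, untested.

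The 25S rRNA control, used among genes only as a covariate in one alternative, stood above the baseline by 4.49 at 20% inhibition and by 4.06 at 30% inhibition. Degradation of RNA would have widened the mean 3′ minus 5′ difference, which changed by only 0.053, though actin alone changed by 0.32 ± 0.09 and GAPDH by −0.12. That measure reads the actin, GAPDH and ubiquitin transcripts, so it does not decide whether the 25S rRNA itself was degraded. In 20% inhibition replicate 3 the 25S control was at 5.25 and the mitochondrial rise was 2.03, a share of 0.932 of the mean rise in the other 3 arrays (2.11 to 2.24). The other 7 arrays of the inhibited states were high in both, but not in the same order. The highest 25S signal among them (13.0, 20% inhibition replicate 1) came with the lowest mitochondrial mean (7.68). The lowest (8.67, 30% inhibition replicate 4) came with a mean of 8.05. Since only 1 array was high in one signal alone, one cause shared with the mitochondrion-encoded transcripts stays open. Carry-over of ribosomal RNA into the labelling and an effect of heat on that RNA were not tested.

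Replicate 3 of 20% inhibition lay apart from the other 3 arrays of its state. On the axis from the 20% to the 30% inhibition mean it stood at 0.590, between the other 20% arrays (−0.006 to 0.099) and the 30% arrays (0.848 to 0.994), which argues against a sample of the 30% state under a wrong label. Its position was nearer the 30% end, where baseline (1.03 to 1.09) and optimum arrays (0.749 to 0.779) lay as well, and its closest array was 30% inhibition replicate 1 by a small margin (correlation 0.9898, against 0.9895 with the closest array of its own state). On the axis from the optimum to the 20% inhibition mean it stood at 0.804, below the others (1.00 to 1.04) and below the 30% arrays (0.916 to 0.965). A weaker heat response of that sample predicted such a position. The other arrays were placed against a 20% mean that includes replicate 3, so the gap is not on one scale. Its small heat shock protein mean (12.15) was below the other 20% arrays but within the 30% range (12.07 to 12.28), and a weaker response stays open. Whether the plant, the leaf temperature or the handling differed was not tested.

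Single arrays stood far from the other 3 of their group in 21 of 372 groups tested, where chance gives about 18.6, and 7 of the 21 were 20% inhibition replicate 3. The values in this paragraph are the gap to the nearest array as a share of the group's range. In that replicate they were 0.985 for AT3G62950 (6.40 against at most 4.13), 0.958 for AT1G55450 (7.79 against 5.94 to 6.02), 0.908 for AT5G47610, 0.884 for AT3G04210, 0.859 for the mean of the chaperones (11.4 against 11.6 to 11.7), 0.850 for COR47 and 0.837 for Hop3. In the other 20% inhibition arrays they were 0.936 for AT1G54050 in replicate 1 and 0.936 for LHCB4.3 in replicate 4. At 30% inhibition they were 0.949 for AT2G29500 in replicate 4, 0.912 for AT1G54050 in replicate 3 and 0.843 for AT1G07050 in replicate 4. At the optimum they were 0.883 for AT4G13550 and 0.863 for AT3G09200 in replicate 3, 0.868 for SWEET2 and 0.849 for CHLM in replicate 4, and 0.831 for ndhH in replicate 1. At baseline they were 0.944 for AT2G41090 in replicate 3, 0.934 for WSD1 in replicate 2, 0.904 for PRA8 in replicate 4 and 0.895 for UGT74B1 in replicate 1.

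Regrouping the arrays asked how often arrays grouped at random give counts as large. Of the 35 splits of each pair of states into 4 and 4 arrays, only the real 1 gave a count as large in each of the 6 comparisons. The highest other split gave 233 against 3770 for the optimum and 223 against 9976 and 0 against 10067 for 20% and 30% inhibition over the baseline. It gave 401 against 9477 and 3 against 9364 over the optimum, and 159 against 1629 between the inhibited states. Of 100 groupings of all 16 arrays, 1, the real one, gave as large an F count (12278, highest other 4483), step count (6318, other 182), number of passing list tests (36, other 34) and shared calls of the optimum with 20% inhibition (2852, other 0) and of both inhibited states (8297, other 0). For the optimum and 30% inhibition, 2 of the 100 gave as many shared calls, the real 2777 and another with 2956. Each count was thus reached in under 5% of the regroupings, without adjustment over these tests, and by a small margin for the list tests. Groupings of all 16 arrays mix the states, so they ask only whether the states differ at all. They cannot tell whether the step pattern or the shared calls would arise from any difference among states.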

How the results depend on the processing

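The 25S rRNA control as a covariate was the alternative chosen only after the data had been seen. It overlaps with the state, so a call lost with it may reflect a wider standard error, a smaller estimate or both. No called value of a named gene or list turned direction under the alternatives run. Centring arrays turned the majority direction of the calls in 4 comparisons: the higher share went from 43.1% to 51.5% (20% inhibition against baseline), 45.0% to 62.1% and 45.1% to 53.6% (20% and 30% against optimum) and 58.5% to 46.4% (30% against 20%). Of 337 alternative counts 313 stayed within 1.5 times and 24 moved; of 421 gene calls 374 held throughout, and of 62 list calls 21.

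With 1 probe set per gene the 6 comparisons gave 1919, 5377 and 5389 against the baseline, 5195 and 5020 against the optimum and 823 between the inhibited states, the F test 6703, the step count 3608 and the shared calls 1456, 1404 and 4415, since fewer features were tested. A 2-fold limit gave 294, 1850, 1848, 1143, 1185 and 82 in the same order, and an adjusted p under 0.01 gave 2061 for the optimum and 728 between the inhibited states, both by construction. Only the 8 arrays compared gave 915 between the inhibited states, with fewer arrays. Passing list tests were 21 without the dimmest genes, 17 with an estimated correlation and 63 with fry; the step count with the 25S covariate was 4068. The cause of these was not tested.

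Without single arrays the counts ran from 2710 to 4479, 9126 to 10040 and 9301 to 10528 against the baseline, 8363 to 9473 and 8498 to 9868 against the optimum and 1178 to 2153 between the inhibited states. The F count ran from 11488 to 12587, the step count from 5530 to 6671, shared calls from 2194 to 3226, 2113 to 3217 and 7618 to 8429, and list tests from 31 to 37. The replicate block gave 1440 between the inhibited states; arrays of the same number had a mean residual correlation of −0.0098. An estimated correlation ended 41 list calls, leaving out the dimmest genes 28, the 25S covariate 8 (among them starch at the optimum, 0.066), array weights 7, repeated quantile normalisation 6 (starch at the optimum, 0.057; antioxidants at 20% and ribosomal proteins at 30% against optimum, 0.051 in both) and the 8-array fit 4 (photorespiration at 20% and the Calvin-Benson cycle at 30% against optimum, 0.054 in both; starch at the optimum, 0.13).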

Other observations

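The families and loci in this part were defined, and their example genes chosen, only after annotation or values had been seen, and no explanation was tested. ATG8D, VPS60.1, bZIP44, IQD24, PRA8, SEC10, AT2G07722 and AT2G07741 stand outside the rule for naming genes and were chosen after their values were seen.

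Autophagy genes (symbols beginning with ATG) passed as a list against the baseline at the preset correlation: 3, 6 and 6 of 8 rose and 0 fell at the optimum, 20% and 30% inhibition, with medians of 0.20, 0.64 and 0.63 (adjusted p = 0.0040, 0.0040 and 0.0048, but adjusted p = 0.39 in each with an estimated correlation). ATG8D rose 2.01-fold, 4.90-fold and 5.25-fold (log2 1.01 ± 0.14, 2.29 ± 0.14 and 2.39 ± 0.14). Vacuolar sorting genes (VPS) passed at the optimum, with 4 of 10 higher and 1 lower (median 0.19, adjusted p = 0.012; 0.19 with an estimated correlation, 0.052 without the dimmest genes), and VPS60.1 rose 2.26-fold there.

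Genes with the symbol stem BZIP passed at 30% inhibition, 7 of 14 higher and 1 lower (median 0.31, adjusted p = 0.033; 0.22 with an estimated correlation, 0.051 without baseline replicate 3), with bZIP44 3.35-fold higher. The calmodulin-binding IQD genes were lower at 30% inhibition, 8 of 15 fell and 0 rose (median −0.22, adjusted p = 0.026; 0.39 with an estimated correlation, 0.057 without the dimmest genes), with IQD24 2.16-fold lower. Genes of the stem PRA were lower at 20% inhibition than at the optimum, 7 of 11 fell (median −0.26, adjusted p = 0.021; 0.39 with an estimated correlation), with PRA8 2.56-fold lower. Secretory genes of the stem SEC were lower at 20% and 30% inhibition than at the optimum, 6 of 8 fell in both (medians −0.33 and −0.36, adjusted p = 0.013 in both; 0.17 with an estimated correlation, 0.14 and 0.12 without the dimmest genes), SEC10 by −0.61 ± 0.07 and −0.74 ± 0.07. The SWEET transporters passed at the optimum, 4 of 14 lower (median −0.15, adjusted p = 0.044), and not with an estimated correlation (0.39) or arrays centred (0.056). That call also ended without baseline replicate 3 or 4 (0.085, 0.054), optimum replicate 1 (0.075) or 20% inhibition replicate 1 or 3 (0.055, 0.053).

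Of 36 loci numbered within the stretch of mitochondrial sequence inserted in nuclear chromosome 2, 22 rose and 0 fell at 20% and at 30% inhibition, with a median of 0.30 and 12 at least 2-fold higher at 30%. AT2G07722 rose 24.3-fold and 37.2-fold and AT2G07741 8.24-fold and 10.7-fold. Whether their probes read the nuclear or the mitochondrial copies was not tested.

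On the axis from the 20% (0) to the 30% inhibition mean (1), made from the probe sets called between those states, the baseline arrays stood at 1.03 to 1.09 and the optimum arrays at 0.749 to 0.779. The 20% arrays set the origin of this axis for every array, so their own noise also moves the others along it.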
